A study of Mus musculus with 2 samples.

How the data were processed

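Long-read RNA sequencing was analysed for 2 libraries of 1 group, the left cerebral cortex of 5xFAD mice aged 8 months. The group and the replicate numbers were taken from the labels. The labels' descriptions call both samples male while their sex field says that sex was not collected, and both samples carry the same donor identifier although they are described as separate biological replicates. Total RNA with SIRV and ERCC spike-ins was sequenced with a PacBio protocol and processed with version 3 of the ENCODE long-read pipeline, per the labels' protocols.

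For each library the authors deposited a table of raw counts of long reads per transcript model and the matching annotation of models. Per the file headers and the text that accompanies each library, reads were aligned to mm10 and assigned to models with GENCODE M21 as the annotation, separately for each library, and the attributes of the models are those of the program TALON. The positions in the deposited annotations are 1-based mm10 coordinates. The aligner, the TALON version and the filters are not given in the sources used here. Every listed model has at least 1 read, replicates were not pooled, and the counts were not normalized by the authors. Each library has its own database, so annotated transcripts were matched by identifier and unannotated models by their chain of introns. Unannotated single-exon models of a gene have no chain and were counted together. The SIRV sequences are annotated as a single-exon gene each, so their model classes were not used.

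Counts were divided by the endogenous total, without spike-ins, and scaled to CPM. The log2 ratio is replicate 2 over replicate 1 with 0.5 CPM added to both. The endogenous totals were 3180094 and 2095837 reads, so a count of 0 allows up to 3 reads, which is 0.943 CPM in replicate 1 and 1.43 CPM in replicate 2. No molecular identifiers are mentioned in the sources, so the intervals and floors cover counting error only. Shares carry exact Clopper-Pearson 95% intervals.

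A quasi-likelihood test has no residual degrees of freedom for 1 library against 1. Genes were therefore compared with a two-sided exact conditional binomial test against the ratio of endogenous totals, over genes with at least 20 reads in both libraries together, with Benjamini-Hochberg adjustment, and were called at an adjusted p under 0.05 and an absolute log2 ratio of at least 1. Isoform composition was tested per gene with a two-sided Fisher's exact test of the major isoform against the rest, in genes with at least 20 reads in each library and at least 2 isoforms. Exon inclusion was the reads of models with the exact exon over reads of models with an exon on both sides of it. It was tested in the same way for internal exons of 75 listed genes with at least 20 spanning reads in each library and a pooled inclusion of 5 to 95 percent. These tests measure how far the libraries lie apart beyond counting error and have no replicate check. Lists of genes were described by their median log2 ratio and its percentile among 10000 random lists of the same size matched on mean expression in 10 classes, and a list stood apart below 2.5 or above 97.5. The correlation of gene levels used log2(CPM + 1).

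The gene lists, tests, thresholds, alternatives and the rule for named genes were fixed before the data were examined, except where stated. There were 35 lists of cell types, pathways, neighbouring brain regions and blood. The rule took the 20 nuclear genes with the highest mean CPM and the sum of mitochondrially encoded genes. Of each list it took up to 4 members with the highest mean CPM, and all members of the transgene-related and Y-linked lists. Among called genes with a mean of at least 20 CPM it took the 10 largest ratios in each direction. Among the 75 genes listed for isoforms it took up to 25 with at least 50 reads in each library and the lowest share on the major isoform, together with App, Psen1, Thy1, Mapt, Bin1, Clu, Apoe, Trem2, Gfap, Snap25 and Mbp, 35 genes in all. For each of these it took the tested exon with inclusion nearest the middle of the range. It also took the 10 most-read NIC or NNC models found in both libraries and the 10 genes with the widest difference in major isoform share. Other called members of lists are named where a list had few calls, after their values were seen.

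Alternatives covered the scaling (edgeR TMM factors of 0.976 and 1.02, DESeq2 size factors of 1.20 and 0.833, spike-in reads), count filters of 1, 10 and 50 reads, the classes of models, pseudocounts, and edgeR's exact test with an assumed coefficient of variation of 0.1 or 0.2. Chosen after seeing the data were the removal of the median ratio of 20 length classes, random lists matched on 10 length and 5 expression classes, thinning of replicate 1 to the depth of replicate 2, single-exon models kept apart by class, a minimum of 10 percentage points for isoforms, a count of lists without 5 of them, and leaving out genes for which at least 10 percent of reads in a library sat on models given to another gene in the other library. The last set held 315 genes, and 0.128% and 0.136% of endogenous reads.

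The tests were tried on simulated counts. For the comparison of genes, 84 of 100 genes changed 3-fold and 93 of 100 changed 6-fold were called, as were 5 of 12078 unchanged genes, among 12273 genes. For isoform composition, 39 of 100 genes shifted by 20 points and 78 of 100 shifted by 40 points were called, and 3 of 9112 unchanged genes, among 9312 genes. Of lists of 20 genes among 12322 genes, 47 of 50 shifted by a log2 ratio of 0.6 and 9 of 100 random ones stood apart. The chi-square per degree of freedom of a simulated pair of identical libraries was 1.01. Software was R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.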

Results

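The series holds long-read RNA sequencing of the left cerebral cortex from adult 5xFAD mice aged 8 months. The 5xFAD strain is an Alzheimer's disease model that carries human APP and PSEN1 transgenes with familial disease mutations, driven by the Thy1 promoter cassette. A single group of 2 libraries, called replicate 1 and replicate 2, was made from total RNA on the PacBio platform, which reads whole cDNAs and so gives the exon structure of each molecule. Replicate 1 held 3232205 reads on 262419 transcript models and replicate 2 held 2120771 reads on 222150 models. After removal of the ERCC and SIRV spike-ins, which took 1.61% and 1.18% of reads, 3180094 and 2095837 endogenous reads remained. Annotated genes received 97.3% and 96.1% of these. The labels name no wild-type or other comparison group, so the values are levels in this tissue with the spread between the libraries, and every test compares the libraries and not a condition. The labels describe separate tissue pieces and separate biological replicates but give both the same donor identifier, so the spread may be technical in part.

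Most of the cortical RNA was read as transcripts already in the annotation. Known models took 73.3% ± 2.16 of endogenous reads (SD, n = 2), with 74.8% in replicate 1 (95% interval 74.8 to 74.9) and 71.8% in replicate 2 (71.7 to 71.8). Models that follow part of an annotated chain of introns, classed as incomplete splice match (ISM), took 9.91% ± 0.150. Models that join annotated splice sites in an unlisted combination (NIC) took 6.07% ± 0.604, and models with at least 1 unlisted splice site (NNC) took 3.51% ± 0.369. Models that overlap a gene without matching its junctions (genomic) took 4.12% ± 0.227, antisense models 2.68% ± 0.782 and intergenic models 0.417% ± 0.0292.

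The class shares differed between the libraries by more than counting error (chi-square 10577.4 on 6 degrees of freedom, Cramér's V 0.0448). Classes were assigned separately for each library, and the same model could be classed differently. The most-read Thy1 model, from 44047470, was ISM in replicate 1 (434 reads) and genomic in replicate 2 (220 reads). A pair of Rapgef4 models changed places between NIC and NNC. Part of the difference may thus lie in labelling, and how much was not measured. Antisense models showed the widest relative gap, 2.13% in replicate 1 against 3.23% in replicate 2. The share of known models depended on what was counted: it was 11.5% of models in place of reads, and 85.2% of reads once ISM and genomic models were left out.

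**Figure D1:**
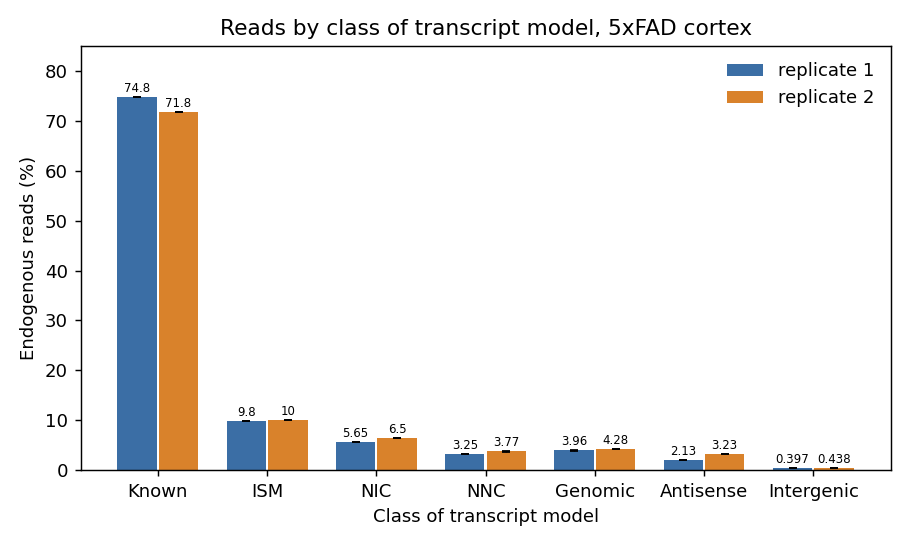
Percent of endogenous reads (vertical axis) in each class of transcript model (horizontal axis) for replicate 1 and replicate 2, with exact 95% intervals as error bars. Known models took 74.8% and 71.8%, and ISM models, the next class, took a mean of 9.91%.

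The most abundant nuclear transcripts came from glia, neurons and housekeeping genes alike. Hspa8, a constitutive chaperone, led with 11592 ± 1787 CPM (reads scaled to the endogenous total, SD, n = 2), followed by the lipid carrier Apoe at 7963 ± 380 and the brain creatine kinase Ckb at 6423 ± 3.27. Mbp, a structural protein of myelin, stood at 6266 ± 1109 CPM, the iron store Fth1 at 5447 ± 234, the tubulin Tuba1a at 4497 ± 736 and the lysosomal protease Ctsd at 4067 ± 193. Between 3992 and 2475 CPM on average followed Cpe, Ubb, Trf, Calm2, Pkm, Rpl3, Ndrg4, Atp1b1, Snap25, Cst3, Aldoc, Aldoa and Calm1. Of these 20 genes only Cst3, a secreted inhibitor of cysteine proteases, passed the threshold between the libraries, at 3622 CPM in replicate 1 and 1781 CPM in replicate 2 (log2 ratio -1.02). Mitochondrially encoded genes of the fixed list summed to 6349 CPM in replicate 1 and 2632 CPM in replicate 2.

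At the loci related to the transgenes, App and Psen1 were read mostly as full-length annotated transcripts, whereas Thy1 was read mostly as single-exon models within its last exon. App (ENSMUSG00000022892.11, chromosome 16, 84949685 to 85173766), which encodes the amyloid precursor protein, stood at 1512 ± 526 CPM from 3623 and 3948 reads. Psen1 (chromosome 12, 83688152 to 83735199), the catalytic subunit of gamma-secretase, stood at 78.9 ± 25.4 CPM from 194 and 203 reads. Thy1 (chromosome 9, 44043384 to 44048579), a neuronal surface glycoprotein, stood at 133 ± 16.0 CPM from 459 and 255 reads. Its single-exon unannotated models, within 44047470 to 44048579 in the last exon, took 94.6% of Thy1 reads in replicate 1 (95% interval 92.1 to 96.4) and 86.7% in replicate 2 (81.9 to 90.6). The full 4-exon model Thy1-201 had 14 and 28 reads. None of App, Psen1 and Thy1 passed the threshold between the libraries, with log2 ratios of 0.73, 0.66 and -0.25. App and Psen1 passed it under spike-in scaling, at 1.19 and 1.12, and with known, NIC and NNC models alone the Thy1 ratio turned to 1.10. The models lie on mouse chromosomes and spike-in sequences, and reads from the human transgenes cannot be told from those of mouse App and Psen1 in these counts.

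**Figure D2:**
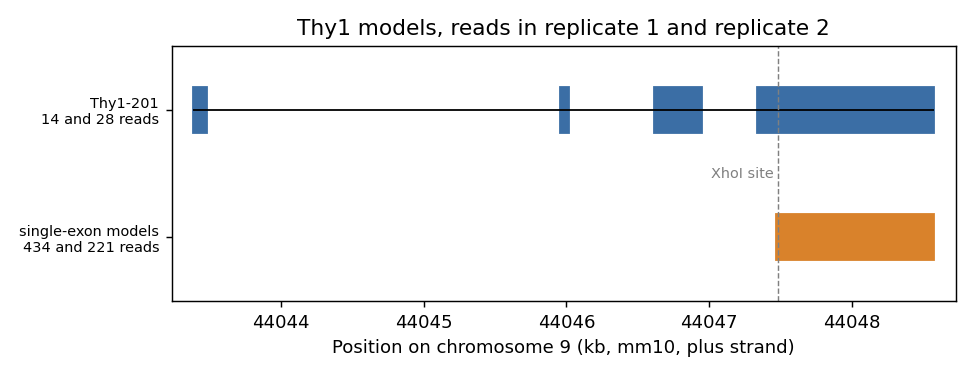
Map of Thy1 on chromosome 9 (horizontal axis, mm10 position in kb), with the exons of the annotated model Thy1-201 above and the single-exon unannotated models below, and a dashed line at an XhoI restriction site. Single-exon models from 44047470 had 434 and 221 reads in replicates 1 and 2, against 14 and 28 for Thy1-201.

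Genes tied to amyloid, tau and disease risk were detected broadly. Of 22 genes of APP processing and tau, all 22 were tested and only Aplp2, an APP paralog, was called higher in replicate 2 (306 and 614 CPM), while Psenen, a subunit of gamma-secretase, was called higher in replicate 1. Apbb1, an adaptor that binds APP, stood at 1175 ± 145 CPM and Aplp1 at 451 ± 7.92. Of 28 orthologs of Alzheimer risk genes, 28 were detected and 24 tested, and only Plcg2 (higher in replicate 2) and Ctsh (higher in replicate 1) were called. The risk list was led by Apoe, Ctsb, the secreted chaperone Clu (523 ± 65.0 CPM) and the transcription factor Mef2c (374 ± 84.4 CPM).

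Neuronal markers covered excitatory, inhibitory and synaptic genes. Excitatory neuron genes summed to 1031 ± 71.7 CPM, with 3 of 13 tested genes higher in replicate 2 (Satb2, Tbr1, Nptx1) and the neuropeptide gene Cck higher in replicate 1 (354 and 144 CPM). Inhibitory neuron genes summed to 1308 ± 154 CPM, of which Gad1, the GABA-synthesising enzyme, gave 732 ± 51.5 CPM. In that list Pvalb, Dlx1 and Dlx2 were higher in replicate 1 and Erbb4 in replicate 2. None of 11 tested cortical layer markers was called, among them Calb1 at 336 ± 76.6 CPM. Presynaptic genes summed to 8119 ± 911 CPM, led by the vesicle fusion protein Snap25 (2739 ± 4.26) and the vesicle protein Syp (1020 ± 289), with only Bsn called among 20. Postsynaptic genes summed to 3182 ± 549 CPM, led by the AMPA receptor subunit Gria2 (671 ± 86.9), with Grin2a and Nlgn2 called higher in replicate 2 among 23. None of 16 immediate early genes was called, and the early response factor Junb stood at 213 ± 11.8 CPM.

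Glial genes were abundant. Astrocyte genes summed to 11921 ± 2381 CPM, with 1 of 18 called (the sodium pump subunit Atp1a2, higher in replicate 2). Gfap, the intermediate filament of reactive astrocytes, stood at 1456 ± 417 CPM, and 4 of 14 genes of the reactive astrocyte list were called, the complement component C4b and the receptor S1pr3 higher in replicate 2, Srgn and Psmb8 higher in replicate 1. Mature oligodendrocyte genes summed to 15532 ± 2620 CPM with none of 20 called. Precursor genes of oligodendrocytes summed to 596 ± 181 CPM with Gpr17 and Tnr called higher in replicate 2 among 11.

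Microglial and immune genes were read in both libraries. The homeostatic microglia list summed to 4964 ± 1399 CPM, with the lysosomal enzyme Hexb at 1266 ± 135 and the receptor Csf1r at 134 ± 56.0, and only Cst3 was called among 16. The disease-associated microglia list summed to 21970 ± 75.4 CPM, mostly Apoe, Fth1, Ctsd and Ctsb, which other brain cells also express. In it Itgax was higher in replicate 2, and Tyrobp, Cd63 and Cd52 in replicate 1. Genes of complement and Fc receptors summed to 1068 ± 245 CPM, with C1qa at 355 ± 137, C4b higher in replicate 2 (38.4 and 98.3 CPM) and Fcer1g higher in replicate 1. Among 15 genes of antigen presentation H2-Aa and Psmb8 were higher in replicate 1, and among 13 interferon response genes Ifi27, Ifi27l2a, Bst2 and Ifitm3 were higher in replicate 1. The lysosome and autophagy list summed to 16221 ± 613 CPM with Gns and Psap higher in replicate 2 among 25.

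Markers of vessels, borders and neighbouring regions were also measured. Endothelial genes summed to 1656 ± 55.4 CPM (Flt1 and Abcb1a higher in replicate 2, Ly6a in replicate 1, of 15) and mural cell genes to 171 ± 12.7 CPM (Pdgfrb higher in replicate 2, of 6). Fibroblast and meningeal genes summed to 1090 ± 246 CPM with none of 6 called, mostly Ptgds. The choroid plexus and ependyma list summed to 1667 ± 119 CPM, of which the thyroid hormone carrier Ttr gave 936 ± 283, with Clic6 higher in replicate 2 and Rarres2 in replicate 1 of 6. Macrophage and lymphocyte markers of the brain borders summed to 25.2 ± 7.58 CPM, with 1 gene, Cd4, deep enough to test and not called. Hippocampal markers summed to 528 ± 160 CPM (Wfs1 higher in replicate 2, of 6) and striatal markers to 1682 ± 211 CPM (none of 10 called), with the striatal signalling inhibitor Ppp1r1b at 526 ± 90.7 CPM. Of 7 thalamic and hypothalamic genes, Lef1 and the glutamate transporter Slc17a6 were higher in replicate 2 and Calb2 in replicate 1. Y-linked genes Ddx3y (68.1 ± 17.1 CPM), Eif2s3y (67.2 ± 14.8), Uty (18.2 ± 4.88) and Kdm5d (6.80 ± 1.17) were read in both libraries, whereas Xist had 0 reads in both, which allows up to 0.943 CPM in replicate 1 and 1.43 CPM in replicate 2. These values go with the labels' descriptions, which call both samples male.

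Over all genes, the ratio between the libraries varied with transcript length, with genes of short transcripts higher in replicate 1. Of 12322 genes with at least 20 reads in both libraries together, 1527 (12.4%) were called different by the exact binomial test, at an adjusted p under 0.05 and an absolute log2 ratio of at least 1, of which 928 were higher in replicate 1 and 599 in replicate 2. The genes higher in replicate 1 had a median transcript length of 914 bases, against 3657 bases for those higher in replicate 2 and 2664 bases for all tested genes. The median log2 ratio (replicate 2 over replicate 1, CPM + 0.5) was -0.66 for 260 genes under 500 bases, -1.13 for 417 genes of 500 to 750 bases, -0.47 for 1303 genes of 1000 to 1500 bases and 0.36 for 1430 genes of 4000 to 5000 bases. Across genes, which are not independent replicates, the ratio and the length had a Spearman rho of 0.456. After the median ratio of 20 length classes was removed, 924 genes were called (411 higher in replicate 1 and 513 in replicate 2), 562 of them among the 1527. Scaling by spike-in reads shifted log2 ratios by up to 0.46 (median 0.45) and gave 2893 calls with 2443 higher in replicate 2 and 450 in replicate 1. The short ERCC spike-ins were themselves lower in replicate 2, so this scale is not free of the length trend. The ratio of replicate 1 to replicate 2 was 1.99 for ERCC reads and 2.27 for SIRV reads. An assumed biological coefficient of variation of 0.2 in edgeR's exact test left 427 calls (384 higher in replicate 1 and 43 in replicate 2). Without a minimum ratio 4439 genes were called, 2037 higher in replicate 1 and 2402 in replicate 2.

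**Figure D3:**
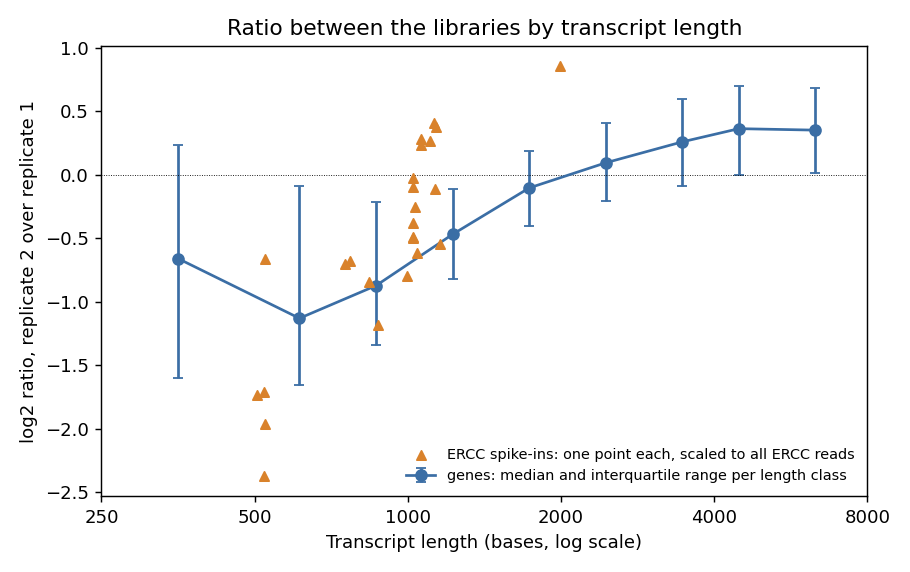
Log2 ratio of replicate 2 over replicate 1 (vertical axis) by transcript length in bases (horizontal log axis), as the median and interquartile range of genes in 9 length classes, and as a point for each of 25 ERCC spike-ins scaled to all ERCC reads. Gene medians are -0.66 under 500 bases, -1.13 at 500 to 750 bases and 0.36 at 4000 to 5000 bases, and the 5 spike-ins under 700 bases have a median of -1.73.

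Among called genes with a mean of at least 20 CPM, the largest single differences included genes of the olfactory system, higher in replicate 1. S100a5 (chromosome 3, 90608523 to 90611780), a calcium-binding protein of olfactory sensory neurons, had 255 reads in replicate 1 and 0 in replicate 2, at least 56.0-fold higher against a floor of 3 reads in replicate 2. Omp (chromosome 7, 98143359 to 98145502), the olfactory marker protein, had 391 reads and 1 read, a ratio of 258 (95% counting interval 46.0 to 10204). With 0.5 CPM added, as in the other folds from here on, Doc2g, a C2-domain protein, was 14.8-fold higher in replicate 1 (142 and 9.07 CPM, exact test adjusted p = 1.91e-71), the fatty acid binding protein Fabp7 11.1-fold (186 and 16.2 CPM), the dopamine-synthesising enzyme Th 6.23-fold (59.1 and 9.07 CPM) and the calcium buffer Calb2 5.32-fold (124 and 22.9 CPM). The short transcripts Gm11518, Rpl35a and Snhg8 were between 5.31-fold and 6.40-fold higher in replicate 1. Klhl10 had 250 reads and 2 reads, a ratio of 82.4 without the added CPM (22.6 to 684), but 249 of its reads sat on a single-exon model at chromosome 11, 100457022 to 100461670, to which replicate 2 gave 160 reads under an unannotated gene.

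The largest differences in the other direction, again among called genes with a mean of at least 20 CPM, were smaller, from 3.12-fold to 6.53-fold higher in replicate 2. Clstn3 (chromosome 6, 124430759 to 124464794), a synaptic adhesion protein, was 3.62-fold higher (67.0 and 244 CPM, exact test adjusted p = 5.09e-61) and Lynx1, a modulator of nicotinic acetylcholine receptors, 3.49-fold (49.7 and 175 CPM). The transcription factor Sox5 was 3.92-fold higher, Itih5 3.54-fold, the matrix protease Adamts4 3.33-fold, the ubiquitin ligase Ubr4 3.21-fold, Myrip 3.15-fold and the receptor Tgfbr2 3.12-fold. Pfkfb2, a regulator of glycolysis, was 6.53-fold and Gm45837 3.61-fold higher, but 47 of 79 and 233 of 617 of their reads in replicate 2 sat on models given to another gene in replicate 1.

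Among 34 lists with enough tested genes, 16 had a median ratio outside the central 95% of random lists matched on expression, 6 toward replicate 2 and 10 toward replicate 1. Toward replicate 1 lay the olfactory bulb list (median log2 ratio -2.70, all 4 tested genes called: Th, Doc2g, Cdhr1 and Calb2) and the blood list (-2.22, 4 of 5 called: the globins Hba-a1, Hba-a2, Hbb-bs and Hbb-bt). Reads of near-identical copies, such as the globin pairs, C4b and its neighbouring paralog or ribosomal protein genes and their pseudogenes, could have been split between copies. Mitochondrially encoded genes (-1.57, 10 of 12 called, such as mt-Rnr2 at 1612 and 503 CPM), cytosolic ribosomal proteins (-1.44, 21 of 26 called, such as Rps6 at 993 and 444 CPM) and nuclear genes of oxidative phosphorylation (-1.39, 17 of 26 called, such as Cox4i1 at 1921 and 765 CPM) lay there too, without Rpl3 (-0.02) or Atp5a1 (0.13). These are lists of short transcripts, with median lengths of 955, 930.5 and 805 bases. The interferon response (-0.80), fibroblast and meninges (-0.57, but 0.27 with all genes of at least 1 read) and complement and Fc receptor (-0.52) lists lay toward replicate 1, as did antigen presentation (-0.42) and disease-associated microglia (-0.23), whose medians changed sign under spike-in scaling to 0.01 and 0.24.

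Toward replicate 2 lay the thalamus and hypothalamus (0.94), oligodendrocyte precursor (0.60), Alzheimer risk (0.45), postsynaptic (0.45), presynaptic (0.42) and astrocyte (0.36) lists. The other lists lay within the matched range: cortical layer markers (0.47), reactive astrocytes (0.45), hippocampus (0.44), excitatory neurons (0.41), striatum (0.39), endothelial cells (0.34), APP processing and tau (0.34), choroid plexus and ependyma (0.19), mature oligodendrocytes (0.18), immediate early genes (0.14) and lysosome and autophagy (0.13). So did the transgene-related loci (0.66). Within the range and with a sign that turned positive under spike-in scaling lay inhibitory neurons (-0.22), heat shock and stress (-0.16, with only Hspa1a called, higher in replicate 2), long noncoding RNAs (-0.10), Y-linked genes (-0.06), mural cells (-0.05) and homeostatic microglia (-0.01). Among the long noncoding RNAs Malat1 (668 and 281 CPM) and Gas5 (156 and 49.1 CPM) were higher in replicate 1 and the imprinted Meg3 (315 and 640 CPM) in replicate 2. The number of genes called when p was adjusted over the list alone equalled the number called over all genes in every list except mature oligodendrocytes (1 against 0) and endothelial cells (4 against 3).

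Against random lists matched on length as well as expression, 14 lists stood apart and 10 did under both kinds of matching: olfactory bulb, blood, mitochondrially encoded, ribosomal, oxidative phosphorylation, interferon response, Alzheimer risk, presynaptic, postsynaptic, and thalamus and hypothalamus. Astrocyte, oligodendrocyte precursor, disease-associated microglia, complement, antigen presentation and fibroblast lists no longer stood apart, while reactive astrocytes, endothelial cells, striatum and the transgene-related loci then did, all toward replicate 2. With known, NIC and NNC models alone the oligodendrocyte precursor and postsynaptic lists no longer stood apart, nor did complement with all genes of at least 1 read.

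Of the 104 list genes called between the libraries, 71 were no longer called after the length trend was removed. Calls were also lost with an assumed coefficient of variation of 0.2 (52) or 0.1 (11), spike-in scaling (32), DESeq2 (10) or TMM factors (8), thinning of replicate 1 (9 of 103 tested), known, NIC and NNC models alone (4 of 95) and no filter on low counts (3). Among the genes named in the text, a log2 ratio under 0.5 in absolute value remained after removal of the length trend for Cck (-0.28), Pvalb (-0.37), Srgn (-0.24), Cst3 (-0.16), Tyrobp (-0.48), Cd63 (-0.49), Fcer1g (-0.45), H2-Aa (-0.45), Ifi27 (-0.36), Bst2 (-0.36), Cox4i1 (-0.46), Rps6 (-0.29), Ly6a (-0.40) and Rarres2 (-0.18). Ratios between 0.5 and 1 remained for Satb2 (0.68), Tbr1 (0.69), Nptx1 (0.71), Erbb4 (0.66), Atp1a2 (0.85), Psmb8 (-0.96), Gpr17 (0.92), Tnr (0.65), Itgax (0.998), Ifi27l2a (-0.65), Gns (0.74), Plcg2 (0.80), Ctsh (-0.89), Aplp2 (0.73), Psenen (-0.51), Bsn (0.96), Grin2a (0.92), mt-Nd4 (-0.92), Clic6 (0.88), Hba-a1 (-0.76), Wfs1 (0.98), Slc17a6 (0.89) and Gas5 (-0.64), so these fell below the threshold with part of the difference left, and Abcb1a (1.09) was lost by its adjusted p of 0.102. With TMM factors the calls of Satb2, Tbr1, Erbb4, Tnr, Gns, Aplp2, Bsn and Meg3 were lost, with DESeq2 factors also those of Nptx1 and Nlgn2, all of which had stood close to the threshold and kept ratios from 0.93 up. Among the named genes, spike-in scaling ended the calls of Cck, Pvalb, Dlx1, Dlx2, Srgn, Psmb8, Cst3, Cd63, H2-Aa, Ifi27, Bst2, Ctsh, mt-Nd4, Cox4i1, Rps6, Ly6a, Rarres2 and Malat1.

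**Figure D4:**
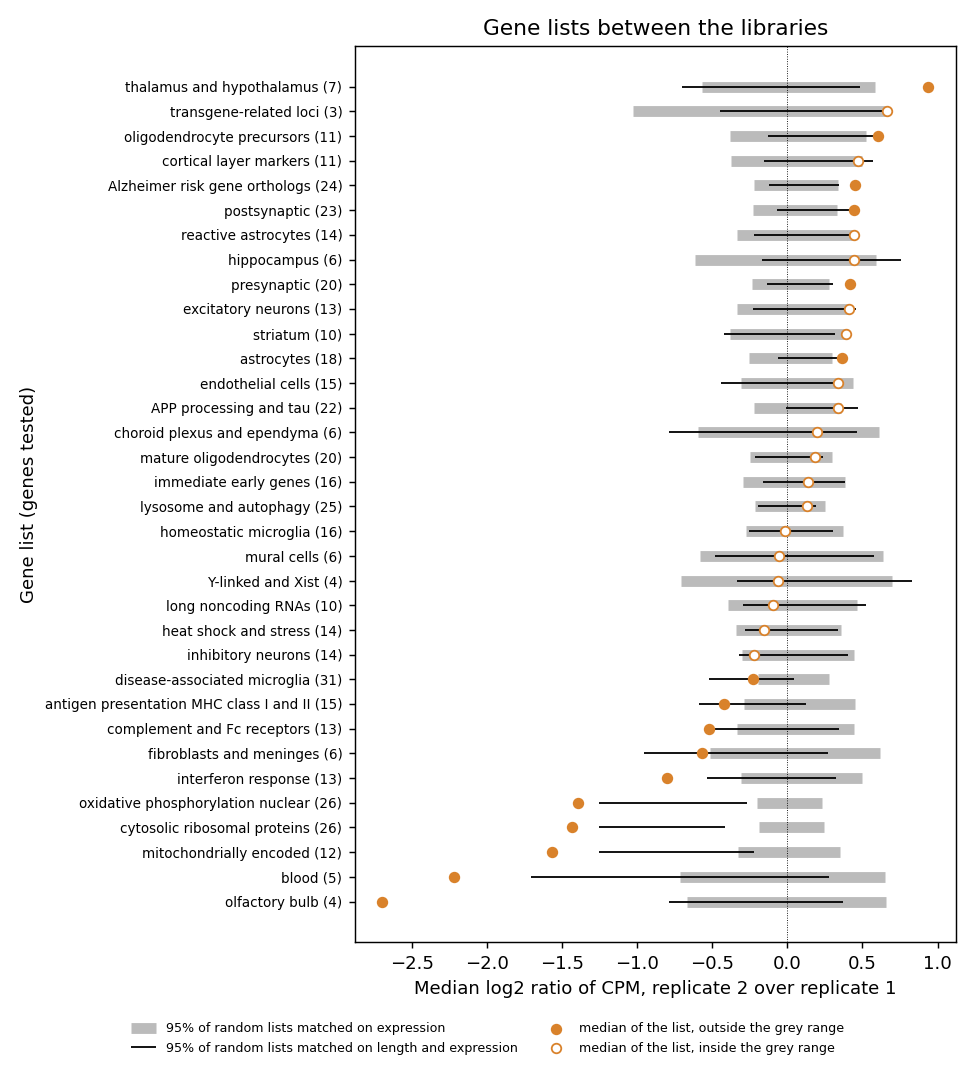
Median log2 ratio of each gene list (horizontal axis, replicate 2 over replicate 1), with the central 95% of 10000 random lists matched on expression (grey bars) and on length and expression (black lines). The olfactory bulb list lies at -2.70 and the thalamus and hypothalamus list at 0.94; under spike-in scaling log2 ratios shift by up to 0.46, so the medians of disease-associated microglia and antigen presentation, as well as 6 lists inside the grey range, change sign.

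Gene levels in the libraries had a Pearson r of 0.962 and a Spearman rho of 0.937 on log2(CPM + 1), across 21714 genes with at least 1 read, which are not independent replicates. The chi-square statistic over genes was 15.3 per degree of freedom (12321 degrees of freedom), which is more than sampling noise gives, so they were not treated as 1 library deposited in 2 copies. It does not tell separate animals from separate preparations of the same RNA.

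Most genes spread their reads over many models, with a majority on the leading one. The median gene with at least 20 reads had 63.8% of its reads on its major isoform in replicate 1 (10822 genes) and 65.0% in replicate 2 (9718 genes), a mean of 64.4% ± 0.838 (SD, n = 2). The median number of models per gene was 14 and 12. The major isoform was an annotated transcript in 7240 of 9312 genes (77.7%). In 1164 (12.5%) it was the gene's unannotated single-exon models, which were counted together. With known, NIC and NNC models alone the median share was 81.1%, and with known models alone it was 97.4%.

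Splice isoforms of synaptic receptors and kinases were shared among several models. The AMPA receptor subunit Gria1 gave 34.8% ± 0.204 of its reads to Gria1-202 and 18.9% to Gria1-201, and Gria2 gave 37.8% ± 3.03 to Gria2-201 and 22.3% ± 1.30 to Gria2-202. The NMDA receptor subunit Grin1 was led by Grin1-205 (27.8% ± 3.81), the presynaptic adhesion gene Nrxn1 by Nrxn1-204 (21.7% ± 4.58) and the calcium-dependent kinase Camk2d by Camk2d-206 (24.0% ± 0.229). For Camk2g the leading model was an NIC model of 21 exons with 23.3% ± 4.72, and the next took 10.6% ± 1.97. Ank2 was led by the annotated single-exon model Ank2-216. Ank3, Ncam1, Nfasc, Map2, Meg3, Homer1 and Sorl1 were led, on the mean of the libraries, by their unannotated single-exon models counted together. For Map2 these took 27.2% and 19.0% of reads. Such models need not be whole transcripts: a single-exon model of Ank3 spans only 76 bases and a single-exon model of Syn1 only 9 bases. In replicate 2 an NIC model of 8 exons led instead in Ank3 (25.8% against 22.1%) and Meg3 (24.3% against 23.8%). Further leading models were Syn2-205 (46.9% ± 4.97), Tpm1-209 (40.1% ± 1.45), Cdc42-202 (48.4% ± 1.76), Ndrg2-202 (46.6% ± 1.08), Gria3-201 (37.6% ± 6.20), Gria4-203 (30.9% ± 1.17), Syn1-202 (35.2% ± 15.3, but behind the gene's single-exon models counted together in replicate 1, with 24.4% against 32.6%) and C4b-201 (37.2% ± 13.2).

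Disease-related genes were mostly read as a single leading transcript. App-201, a 16-exon model, took 76.9% of App reads in replicate 1 (95% interval 75.5 to 78.3) and 82.2% in replicate 2 (81.0 to 83.4). Psen1-201 took 77.5% ± 4.64, Clu-201 69.8% ± 3.85, Gfap-201 83.1% ± 2.77 and Apoe-206 96.7% ± 0.238. Reads of the human transgenes cannot be told from those of mouse App and Psen1 in these counts. The App and Psen1 shares, and the App difference between the libraries given below, may thus include them. The microglial receptor Trem2 gave 77.1% ± 1.89 to Trem2-201, 13.4% ± 0.180 to Trem2-202 and 5.37% ± 0.960 to the intron-retaining Trem2-203. Mapt, which encodes tau, gave 53.0% ± 5.31 to Mapt-204. Bin1, a membrane-bending adaptor and risk gene, was split between Bin1-205 (27.8% ± 4.23) and the longer Bin1-201 (20.8% ± 1.86). In myelin genes, Mbp-211 took 75.7% ± 6.22 of Mbp reads, and an NIC model of 12 exons took 41.8% ± 2.54 of Mag reads.

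Isoform composition was called different between the libraries in few of the genes tested. On simulated counts the test found 39 of 100 genes shifted by 20 points and 78 of 100 shifted by 40, so many shifts may go uncalled. Fisher's exact test of the major isoform against all others called 268 of 9312 genes after adjustment (1161 at an unadjusted p under 0.05), and 155 of these differed by at least 10 percentage points. Among the named genes Ntrk2, the BDNF receptor, gave 44.7% and 31.0% of reads to the 12-exon model Ntrk2-202 (exact test, adjusted p = 1.17e-05) while its longer 18-exon model took 6.29% and 13.7%. Snap25-201 took 78.9% and 88.0% (exact test, adjusted p = 9.17e-44) and Mbp-211 71.3% and 80.1% (exact test, adjusted p = 3.25e-71). App, Gfap, C4b, Map2 and Thy1 were also called, with exact test adjusted p of 2.52e-06, 0.000915, 0.0389, 0.0168 and 0.0194. For Map2 and Thy1 the tested share was that of their unannotated single-exon models counted together. The length trend was not removed in this test. Snap25-202, lower in replicate 2, has 1014 bases against 2116 of Snap25-201, and Ntrk2-202 has 6846 against 8744 of the longer model. The lower Mbp-212 is the longer, with 2056 bases against 1922 of Mbp-211. For Snap25 splicing and the length trend cannot be told apart. Both Ntrk2 models lie in the class of genes from 5000 bases, whose median log2 ratio was 0.35, against 0.36 at 4000 to 5000 bases. The gene trend thus did not rise between these classes. Lengths within the longest class were not compared, so for Ntrk2 a length effect is not excluded. The widest shift outside genes assigned differently in the libraries was in BC017158, whose model BC017158-201 took 12.5% and 66.7%, followed by Haus5-201 (92.3% and 38.7%) and Gpsm1-211 (65.0% and 16.8%, exact test adjusted p = 1.49e-31). Npcd (57.9% and 11.1%) and Btbd19 (12.2% and 58.3%) were next. Except for Gpsm1 these rest on few reads. The leading model had 3 and 14 reads in BC017158 (21 and 7 on the rest), 24 and 12 in Haus5 (2 and 19), 22 and 3 in Npcd (16 and 24), and 5 and 14 in Btbd19 (36 and 10). Ccdc159, Ece2, Zfp868, Gm49325 and Zfp512b also ranked among the 10 widest, but between 30.3% and 55.7% of the reads of each in a library sat on models given to another gene in the other library. With known, NIC and NNC models alone 72 genes were called, 39 of them among the 268, with Ntrk2, Snap25 and Mbp. App (91.2% and 92.7%), Gfap (88.3% and 89.6%), C4b (64.2% and 73.3%) and Map2 (21.2% and 23.5%) were then not called. Nor was Thy1, with 66.7% and 93.3% on Thy1-201 from 14 and 28 reads. When unannotated single-exon models were kept apart by class, 427 genes were called. These include differences of labelling, such as Thy1 at 94.6% and 0%, since a model's class could differ between the libraries.

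Inclusion of alternative exons was close in the libraries for most receptor genes. An exon of 115 bases of the mutually exclusive flip and flop pair was included in 63.6% ± 0.831 of spanning Gria2 reads and 62.7% ± 0.383 of Gria1 reads, and Gria3 included its own in 26.6% ± 2.49. Grin1 included a coding exon of 111 bases (chromosome 2, 25294438 to 25294548) in 32.9% ± 0.0555 and Nrxn1 a coding exon of 88 bases in 56.6% ± 1.16. Mapt included a coding exon of 87 bases (chromosome 11, 104287123 to 104287209) in 19.4% of 413 reads and 24.0% of 262 reads. For Ndrg2 an exon of 42 bases stood at 23.7% ± 0.223, for Trem2 an exon of 185 bases at 85.4% ± 0.714, for Mag an exon of 45 bases at 73.6% ± 1.95 and for Camk2d an exon of 89 bases at 43.4% ± 2.26. None of these passed the test between the libraries, nor did the named exons of Ank2, Ank3, C4b, Homer1, Meg3, Ncam1, Nfasc, Thy1 and Tpm1.

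Fisher's exact test called 21 of 138 exons, in 12 of 43 genes, after adjustment (26 at an unadjusted p under 0.05). Snap25 has a pair of mutually exclusive exons of 118 bases, and the downstream exon (chromosome 2, 136770057 to 136770174) was included in 85.8% of 8247 reads and 93.7% of 5571 reads (exact test, adjusted p = 3.98e-49). Mbp included a coding exon of 123 bases in 17.5% and 11.4% (exact test, adjusted p = 1.17e-51). Bin1 included a coding exon of 93 bases in 44.3% and 55.1% (exact test, adjusted p = 0.00157), Camk2g an exon of 63 bases in 58.2% and 65.8%, and Map2 its coding exon of 3741 bases in 63.1% and 79.3% (exact test, adjusted p = 0.00202). The length trend was not removed from this test either. For the long Map2 exon, higher in replicate 2, it cannot be told apart from a difference of splicing. The same holds for Snap25, whose isoforms named above differ in length. The 5 called exons that differed by at least 10 points were those of Bin1 and Map2, an exon of 24 bases in the GABA receptor subunit Gabrg2 (54.4% and 66.6%) and a pair of overlapping exons of 114 and 123 bases in the calcium sensor Syt1 (39.3% and 52.2%, 60.7% and 47.5%). The remaining called exons lay in Camk2b, Camk2d, Plp1, Pkm and Ndrg4, or were further exons of the genes above. Gabrg2, Syt1 and these genes were named after their values were seen. Known models alone left 10 exons called, without the Bin1 exon (exact test, adjusted p = 0.0821), and the Map2 call was lost with known, NIC and NNC models (exact test, adjusted p = 0.590).

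**Figure D5:**
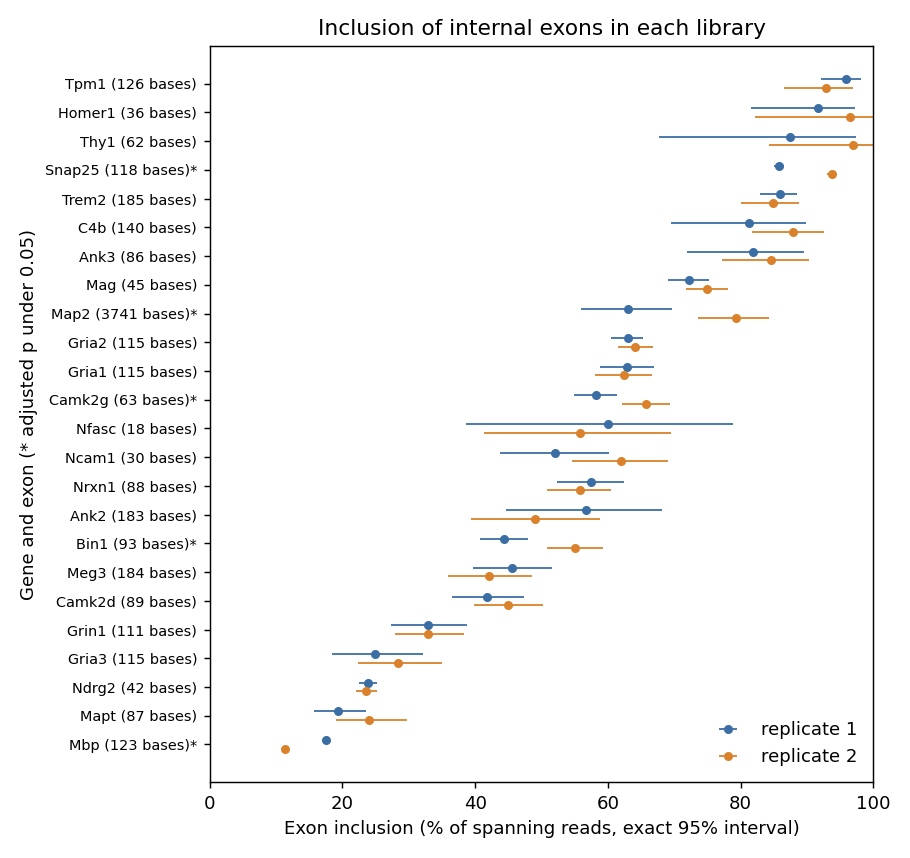
Inclusion of 24 internal exons (horizontal axis, percent of spanning reads) in replicate 1 and replicate 2, with exact 95% intervals, by gene and exon length. Asterisks mark adjusted p under 0.05 in Fisher's exact test: Snap25, Map2, Camk2g, Bin1 and Mbp.

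Unannotated splice forms with more than a few reads were seen in both libraries. Of NIC and NNC intron chains with at least 2 reads, 67.9% of 27320 in replicate 1 were found in replicate 2, and 78.3% of 20906 in replicate 2 were found in replicate 1. The mean of these directions was 73.1% ± 7.40, where the SD is between directions of the same overlap and not a spread between replicates. The mean shares were 33.0% for chains with at least 1 read, 96.8% from 5 reads and 99.8% from 20 reads. The most-read unannotated model was a 13-exon NIC model of the septin gene Sept7 with 2455 and 1477 reads, 72.9% and 75.5% of the gene's reads. Unannotated models also held most reads of Oaz2, an antizyme of polyamine synthesis (88.7% and 88.9%), the ESCRT gene Chmp1a (88.4% and 89.7%), the chaperonin subunit Cct6a (86.2% and 87.0%), the dynactin subunit Dctn2 (1566 of 1927 and 912 of 1112 reads) and Apbb1 (55.1% and 58.0%). An NNC model of the neuropeptide gene Penk (chromosome 4, 4132792 to 4138819) took 94.0% and 96.4%. A pair of models of Rapgef4, an exchange factor for Rap, took 40.9% and 38.1% in replicate 1 and 41.5% and 41.4% in replicate 2, and a model of Hnrnpk took 31.2% and 34.4%.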

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

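All tests in this part were chosen after the patterns they address were seen, and the values of the ERCC spike-ins were also known before their test was written down.

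Reads of antisense and intergenic models entered the comparison of class shares but not those of genes, isoforms or exons, and are given here because their counts were above what a count of 0 allows, which with so many reads says nothing more about them. Antisense models took 2.13% of endogenous reads in replicate 1 and 3.23% in replicate 2, against 1.33% (95% interval 1.21 to 1.47) and 1.01% (0.859 to 1.18) of reads in antisense orientation on the ERCC spike-ins. Intergenic models took 0.397% and 0.438%. The largest antisense locus, on the plus strand of chromosome 13 from 99421446 to 99424415, opposite exons of the microtubule protein gene Map1b, had 3223 reads in both libraries (1215 and 2008). A locus on the minus strand of chromosome 2, 158381062 to 158384917, opposite the long noncoding RNA Snhg11, had 3007 reads (1716 and 1291). On the plus strand of chromosome 17, 39846353 to 39846958, next to Gm42418 and opposite CT010467.1, 1857 reads were split unevenly (1706 and 151). On chromosome 9, 52671761 to 52676802, opposite AI593442, there were 1708 reads (905 and 803). The largest intergenic loci lay on the minus strand, on chromosome 11 from 20334834 to 20335012 next to Gm12033 with 2025 reads (1202 and 823) and on chromosome 6 from 126636465 to 126640397 next to the potassium channel gene Kcna1 with 173 reads (79 and 94).

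Genes with short transcripts were higher in replicate 1. Low counts at the lower depth of replicate 2 are argued against, since among genes with at least 200 reads in each library the median log2 ratio was -1.30 for 95 genes under 1000 bases (interquartile range -1.65 to -0.53) and 0.23 for 1488 from 2000 bases (-0.03 to 0.49), a difference of -1.53, whereas the 80.0% of called genes that remained called after thinning replicate 1 covered all lengths and decides nothing on greater depth. The ERCC spike-ins, added to both libraries as a mix of fixed composition, carried the same trend: the median log2 ratio was -1.73 for 5 spike-ins under 700 bases (range -2.37 to -0.67) and -0.10 for 16 from 900 bases (range -0.80 to 0.85), a difference of -1.63, consistent with length selection during library preparation. The spike-ins under 700 bases had 505 to 523 bases and those from 900 bases had 994 to 1156, except ERCC-00025 with 1994. They therefore do not cover the further rise of the gene ratio, to 0.36 at 4000 to 5000 bases. Whether respiratory and ribosomal protein genes, as 1 set, were also lower apart from length cannot be told apart: the higher of their percentiles among length-matched lists was 0.29, which met the criterion set beforehand, but length classes leave length differences within them. Against the 100 genes nearest in length, a comparison added after the percentile was seen, respiratory genes had a median difference of -0.29 (interquartile range -0.52 to 0.04, 19 of 26 below). Ribosomal genes had -0.52 (-0.996 to -0.35, 24 of 26 below). These ranges give the spread among genes and not the uncertainty of a median, so 0 within the respiratory range decides nothing. Most members of both lists lay below genes of their length. No test was made of these differences, from 1 library against 1, so the question stays open.

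Olfactory bulb markers were higher in replicate 1. Length selection is argued against as the whole cause, because the list lay at percentile 0 of random lists matched on length and expression. A second list of 20 olfactory bulb genes, written before its values were seen, also lay at percentile 0 of such lists (median log2 ratio -1.21 over 16 tested genes, 95% of random lists between -0.35 and 0.37, and -1.21 with genes of 0 reads at their bound), with 10 genes called higher in replicate 1 and 0 in replicate 2. Its most abundant genes were Synpr (577 and 280 CPM), Meis2 (240 and 176), Gng13 (92.5 and 30.1) and Dlx1 (46.5 and 19.6), the last also in another list (inhibitory neurons), and 12 of the 20 had more than 3 reads in replicate 2. Some olfactory bulb tissue in the replicate 1 dissection may therefore be a candidate source, as a hypothesis, and the design, with 1 group, gave no biological explanation to test.

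Thy1 reads began inside its last exon. Its single-exon share lay at percentiles 99.9 and 99.6 of 3940 genes, whose medians were 2.61% and 1.89%. That share had prompted the test, so the comparison shows only that it exceeded the share of most other genes. It is not counted as an argument against incomplete cDNAs, and a truncation point particular to Thy1 was not tested and stays open. For transcripts of the Thy1 transgene cassette, the part aligned to the Thy1 last exon was predicted to begin near the cassette's XhoI cloning site. The most-read model began 11 bases from the XhoI site at 44047481 in both libraries. This was beyond the bound of 10 bases set beforehand, so by that bound the test went against the cassette. The cassette stays open, by a clause added after the distance of 11 was seen. The start at 44047470 was also a splice acceptor of another model in each library and may have been taken over from it. Such a takeover was not tested, and the reads behind that acceptor are not given here. For scale, a 2-exon NNC model of Thy1 had 3 and 1 reads, against 434 and 221 for the single-exon models. The sequence of the cassette junction is also not in the sources used here. Both libraries come from the transgenic strain, so no group without the transgene was compared.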

How the results depend on the processing

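No paired analysis was possible because the labels give 1 group, and the cause of a change below was not tested except where a setting by construction tests fewer models or asks for less or more. Chosen after seeing the data were length correction, length-matched lists, single-exon models kept apart, the minimum of 10 points, thinning, the smaller set of lists and leaving out genes assigned differently. The share of reads in known transcripts was 11.5% as a share of models, 85.2% without genomic and ISM models, 77.5% for models with at least 2 reads, and 71.8% to 74.8% with either library left out. Genes differing numbered 2893 with spike-in scaling (84.4% higher in replicate 2, against 39.2% of 1527, with 1049 kept), 4439 without a minimum ratio, 427 with a coefficient of variation of 0.2, 924 after length correction, and 1188 to 1575 under the others. TMM and DESeq2 moved log2 ratios by a median of -0.07. Genes with differing isoform composition numbered 72 with known, NIC and NNC models, 427 with single-exon models kept apart, 155 with at least 10 points, and 238 to 295 otherwise. The median share of the major isoform was 81.1% with known, NIC and NNC models, 97.4% with known models, 68.7% from 50 reads, 63.0% from 10 reads, and 63.8% to 65.0% with either library left out. Shared intron chains made up 33.0% from 1 read, 96.8% from 5 and 99.8% from 20 reads, and 67.9% to 78.3% by direction of matching. Known models alone left 10 exons differing, with 21 under the others. Spearman rho and Pearson r of gene levels were 0.922 and 0.925 from 20 reads, 0.937 and 0.905 with 0.1 added, 0.937 and 0.968 with 5 added, and 0.927 and 0.957 with known, NIC and NNC models. The chi-square per degree of freedom was 18.7 from 50 reads and 16.9 with known, NIC and NNC models. Lists standing apart numbered 14 to 20, and 11 of 29 without the olfactory bulb, blood, ribosomal, oxidative phosphorylation and mitochondrial lists. The direction turned for Thy1 (1.10 with known, NIC and NNC models, 0.21 with spike-in scaling) and for fibroblasts and meninges (percentile 77.3 with all genes of at least 1 read). Disease-associated microglia kept their median when matched on length but moved to percentile 51.9. The side of the threshold, and the direction of values past it, held under all alternatives run for 108 of 153 genes taken by the rule, 18 of 34 lists and 21 of 23 named exons. The direction of all values held as well for 63, 16 and 16. List members named after their values were seen are not among the 153 unless the rule also took them. Spike-in scaling, which moved log2 ratios by up to 0.46, changed the sign of 8 list medians. Depth limits genes near 0.943 and 1.43 CPM, and chains of 1 read.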

Other observations

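The tests in this part that remove a length trend were chosen after the result was seen. Several exons outside the rule for names, chosen after their values were seen, differed in inclusion between the libraries. The glycolytic enzyme gene Pkm has a pair of mutually exclusive exons of 167 bases, and the upstream exon was included in 84.7% and 87.7% of reads and the downstream exon in 1243 of 8330 and 950 of 7914 reads. The myelin gene Plp1 used the longer of its overlapping exons, of 262 bases, in 71.4% and 75.2% and the shorter, of 157 bases, in 28.6% and 24.8%. Ndrg4 included an exon of 39 bases in 84.8% and 93.9% (exact test, adjusted p = 3.93e-71), and Camk2b an exon of 75 bases in 93.1% and 97.2%.

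Globin genes were compared after removal of the length trend. Hba-a2, Hbb-bs and Hbb-bt had length-corrected log2 ratios of -1.20, -1.34 and -1.63 and stayed called, while Hba-a1 had -0.76 and did not. Malat1, a nuclear noncoding RNA of 6983 bases, went against the length trend, with a log2 ratio of -1.25 and of -1.61 after length correction.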
